A study of Brassica napus with 12 samples.

How the data were processed

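RNA was measured in the first true leaf of seedlings of 2 cultivars of Brassica napus (oilseed rape), Avatar and Zhongshuang 9, after 24 h of full submergence or 24 h in air. The plant is an allotetraploid: each cell carries the chromosomes of an A and of a C subgenome, and many genes are present as a closely related A and C copy. Per the labels' protocols, seeds germinated for 24 h at 30 °C in darkness, plants then grew in 8 h days at about 23 °C and 100 µmol photons of light per square metre per second. Treatment began on day 15, 2 h into the light period. Per the labels' protocols, libraries kept the strand of the RNA through dUTP marking and were sequenced on an Illumina instrument; the strand setting used in counting is not given in the sources used here.

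The deposited values are estimated counts and TPM (length-scaled abundances with the same total in each library) for 101040 coding sequences in each of 12 libraries, and their columns are those kallisto writes. The submitters' processing notes name kallisto, edgeR and limma without versions. The genome build and the annotation behind the identifiers are not given in the sources used here. All target lengths are multiples of 3, so lengths are coding lengths. Between 61980 and 64650 targets per library had a value above 0. Of all deposited estimated counts, values of 0 included, 36.4% were not whole numbers, because kallisto divides reads that fit several targets between them. Values of near-identical copies, among them A and C copies of a gene, are therefore uncertain individually. Counts per library summed to between 24389813 and 35873196. A count of 0 allows up to 3 counts, which is between 0.0836 and 0.123 CPM (counts scaled to a common library total) in a single library. Such floors and all intervals on counts cover counting error only.

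Each library was placed in its group by cultivar and treatment from the labels, with 3 libraries in each of 4 groups. Nothing in the labels says whether a library holds a single plant or several plants, or whether replicates come from separate sowings. P-values of tests between libraries therefore measure only the spread between these samples. No pair of libraries agreed within sampling noise: the smallest chi-square per gene between libraries was 5.06, against a value of 1 for counting noise alone.

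Estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 55674 of the 101040 targets, 26280 on A and 29235 on C chromosomes. Libraries were scaled by TMM factors, which lay between 0.852 and 0.919 in air and between 1.08 and 1.202 under submergence. edgeR's quasi-likelihood F test was run in a model with a mean for each of the 4 groups over all 12 libraries. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The 5 contrasts were submergence against air in each cultivar, the difference between these responses (the interaction), and Zhongshuang 9 against Avatar in air and under submergence. Standard errors of log2 fold changes were derived from the fold change and its F value. CPM values of named genes use the TMM-scaled library sizes. Odds ratios between subgenomes come from Fisher's exact test, two-sided, and the 15 such tests were adjusted together by Benjamini-Hochberg. Fisher's exact tests, here and for genes inside segments, count genes as independent. Genes share the same libraries and neighbours can shift together, so the p-values and intervals of these tests do not measure the spread between samples.

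Identifiers were joined to a RefSeq gene table of the Da-Ae assembly. Of the 101040 identifiers, 3347 (3.31%) matched, and only 2 of them carried a gene symbol besides a locus name. The 34 gene lists that had been fixed before the data were examined, on fermentation, photosynthesis, hormones and other functions, could therefore not be evaluated, and genes are named by identifier. By the rule fixed for this case, the text names per comparison at most 2 identifiers that rose and 2 that fell. For submergence and for cultivar these have the largest averaged log2 fold change among genes past the threshold in both contrasts in the same direction, with a mean of at least 5 CPM in the higher groups. For the interaction they have the smallest p, with at least 5 CPM in the highest group. The genes behind the 2 symbols are reported as well, chosen after their values were seen.

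Each identifier names a chromosome and a gene number. Among 2939 matched genes placed in both sources, 2732 (93%) lay on the same chromosome in Da-Ae, and the absolute rank correlation of gene number with position had a median of 0.862 over 19 chromosomes and a lowest value of 0.779. Gene number was therefore used as order along a chromosome. For the search for segments, chosen after the data were examined, genes with a mean log2 CPM above 1 (with 2 counts added) were divided along each chromosome into 743 blocks of about 40 genes. The deviation of a gene in a library was its log2 CPM minus the median of the other 5 libraries of the cultivar, after removal of the treatment effect of each gene in the other cultivar, centred within each block. A segment was a run of at least 3 blocks whose median deviated by at least 0.6 in the same direction, or a run that held a block lower by at least 2. Gene positions were shuffled 100 times to see how many segments chance gives. A gene was taken as counted where it had at least 2 CPM and as silent where it had at most 2 counts. A segment is called silent where the median of its blocks was lower by at least 2, so it can include blocks that were lowered only.

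The tests were run on simulated counts with the real dispersions and library sizes and a single mean per gene over all libraries. No real difference between groups was thus present. The changed genes were drawn only from genes with a mean of at least 5 CPM, and recovery below that level was not tested. With 200 genes changed among 54100 tested, the test of the submergence response in Avatar recovered 59.1% of 66 genes changed by 4-fold and 4.5% of 67 genes changed by 2-fold. The median log2 sizes were 2.02 and 0.98, and 0 of the 42 calls were unchanged genes. With so few changed genes the adjusted threshold is stricter than in the data. For the interaction it recovered 33.3% of 66 genes changed by 4-fold and 0 of 67 changed by 2-fold among 54214 genes, and 4 of its 26 calls were unchanged genes. The segment search, run on 31725 simulated genes, found a stretch of 160 genes lowered to a share of 0.5 in 1 library, at a median of -0.98, and no segment in the unchanged libraries.

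Alternatives fixed before the data were examined were RLE size factors, library totals alone, DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2 of the deposited TPM with 1 or 0.1 added. Further ones were other filters on low counts, the replicate number as a block, only the libraries compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Leaving out the libraries or genes of the segments was added after the data were examined.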

Results

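The leaf transcriptome of Brassica napus was compared between air and 24 h of full submergence in the cultivars Avatar and Zhongshuang 9, to ask how each responds and whether their responses differ. First true leaves of 16-day-old seedlings gave 12 libraries, 3 for each cultivar and treatment, with 24389813 to 35873196 estimated counts each. Of 101040 annotated coding sequences, 55674 had enough counts to be tested, 26280 of them in the A subgenome and 29235 in the C subgenome. Replicates carry the numbers 1, 3 and 4 in every group.

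Treatment and cultivar separated the libraries. The first principal component of log2 CPM held 39.6% of the variance and parted air from submergence within each cultivar. The second held 31% and parted the cultivars within each treatment. Counts were spread over more genes under submergence: the 20 highest targets held 7.94% ± 0.53 (SD, n = 6) of the counts, against 10.79% ± 0.63 (SD, n = 6) in air (exact permutation test, two-sided, p = 0.00216). At least 1 CPM was reached by 40294 to 42960 targets under submergence and by 38843 to 39531 in air. The A subgenome held 49.65% ± 0.87 (SD, n = 6) of the counts in Avatar and 47.28% ± 1.08 (SD, n = 6) in Zhongshuang 9 (exact permutation test, two-sided, p = 0.00433). Part of this gap lay in the libraries with shifted chromosome segments described below. In Avatar those held 50.03% to 51.04% and the others 48.86% to 49.03%. In Zhongshuang 9 those held 48.9% (air replicate 4) and 45.72% (submergence replicate 1), and the others 46.79% to 47.74%. Zhongshuang 9 submergence replicate 1 stood apart, with a rank correlation across genes of 0.89 to each of the other replicates of its group, which correlated at 0.988 with each other.

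**Figure D1:**
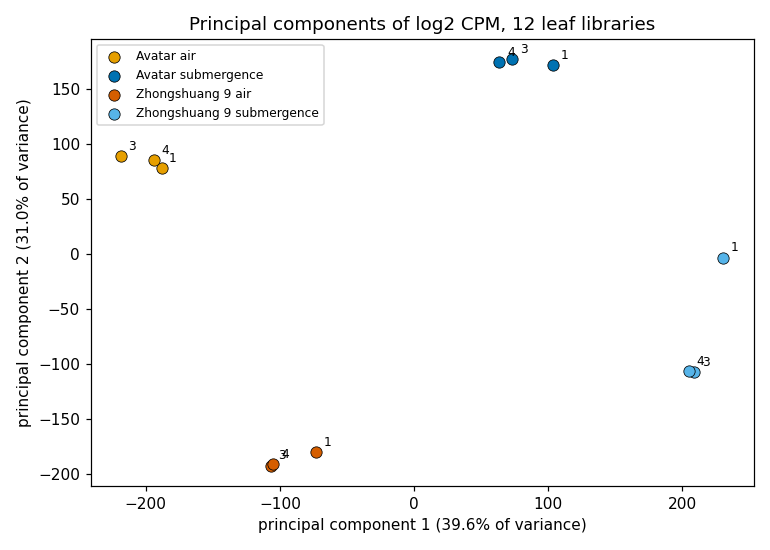
Principal components 1 and 2 of log2 CPM for the 12 libraries, each point a library, coloured by group and marked with its replicate number. Component 1 (39.6% of variance) parts air from submergence within each cultivar, component 2 (31%) parts the cultivars, and Zhongshuang 9 submergence replicate 1 lies apart from replicates 3 and 4.

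Long stretches of neighbouring C subgenome genes were silent or lowered in single libraries. In Avatar air replicate 3, the start of chromosome C02 (gene numbers 40 to 8730) stood at 1.3% of the level in the other Avatar libraries, and 141 of its 240 expressed genes had at most 2 counts. On C03 of the same library, genes from 1890 to 19100 stood at 1.6%, with at most 2 counts for 361 of 560 genes, and the blocks before them were lowered but not silent, with median log2 shifts of -0.74 and -0.88. The start of C02 was also silent in Zhongshuang 9 submergence replicate 1, at 1.6% of the usual level. In the same libraries A chromosomes were raised. Genes at the start of A02 stood at 176.1% in Avatar air replicate 3 and 207.6% in Zhongshuang 9 submergence replicate 1. Genes of A03 between gene numbers 1970 and 15290 stood at 197.9% in Avatar air replicate 3. Other stretches were lowered but seldom silent. In Avatar air replicate 4, 640 genes of C03 from gene number 10 to 19100 stood at 53.2%, and 120 genes further along C03 at 46.2%. Most of C08 from gene number 14280 on stood at 53.3% and 50.2% over 520 genes each in Avatar submergence replicate 1. Nearly the whole of C08 was lowered in Zhongshuang 9 air replicate 4, to 53.3% over 840 genes and 54.7% over 708 genes. Avatar submergence replicate 1 also had the start of C02 at 58.1% and a stretch of A07 at 61.9%, and Avatar air replicate 4 had a single block of C02 at 16.3%. Zhongshuang 9 submergence replicate 1 further had 400 genes of A06 at 52.2%, 120 genes of A08 at 53.1% and 40 genes of C08 at 2.6%. There were 18 such segments in 5 of the 12 libraries, and none in any of 100 shuffles of gene positions. Summed over libraries, so that a gene counts once for each library in which it is shifted, they held 6308 genes. Blocks of 20 genes gave 39 segments in 6 libraries (sum 6108), with Avatar submergence replicate 3 added by 1 lowered segment of 60 genes. Blocks of 80 genes gave 11 segments in 5 libraries (sum 6056), and a minimum shift of 0.8 gave 19 segments in 5 libraries (sum 4428).

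**Figure D2:**
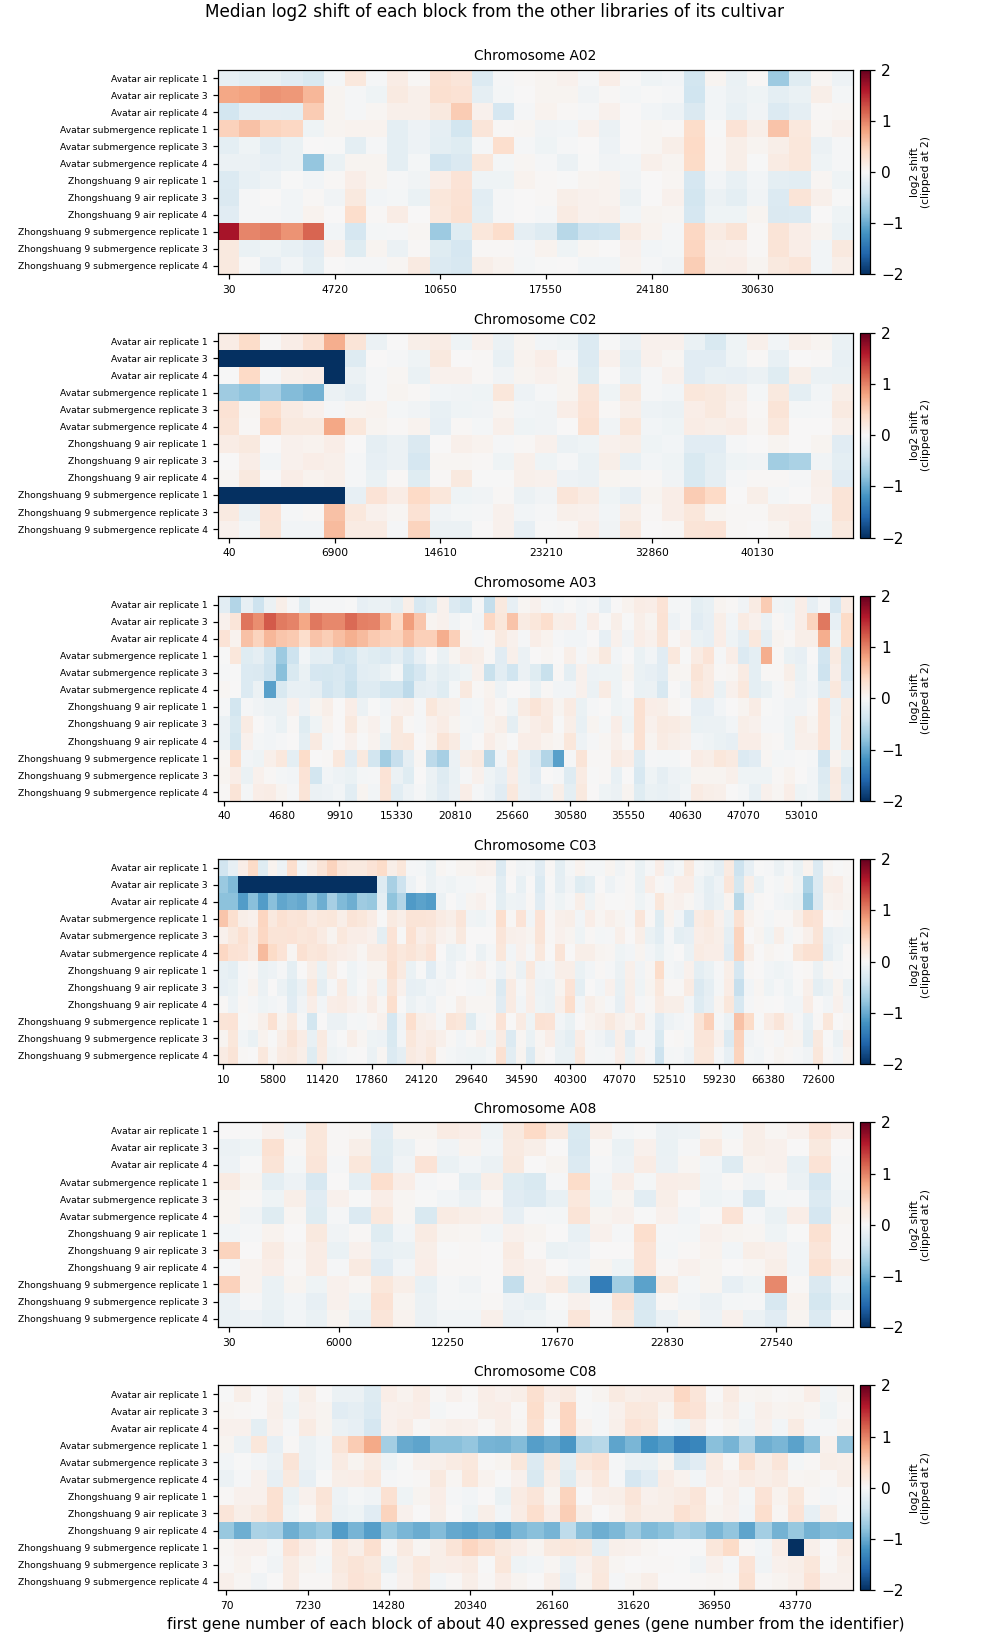
Median log2 shift of blocks of about 40 neighbouring expressed genes from the other libraries of the same cultivar, for the 12 libraries (rows) along 6 chromosomes (horizontal axis, first gene number of each block); blue is lower, red is higher, and shifts beyond 2 are drawn as 2. The start of C02 and a stretch of C03 are silent in Avatar air replicate 3, where A02 and A03 are higher, and C08 is lower along its length in Zhongshuang 9 air replicate 4, at about 53.3% of its level.

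Submergence changed a large part of the Avatar leaf transcriptome: 12009 genes rose and 10259 fell, 40% of those tested (edgeR quasi-likelihood test). Of these, 14427 changed at least 2-fold. BnaC09g10140D and BnaA08g26000D, the largest risers common to both cultivars, had no count in any Avatar air library and reached 29.4 ± 21.5 and 10.4 ± 6.35 CPM under submergence (SD, n = 3). With a floor of 3 counts per library they were at least 269-fold and at least 95.3-fold higher. BnaA07g33410D fell from 73.0 ± 10.6 CPM and BnaA05g06830D from 8.81 ± 2.38 CPM (SD, n = 3) to no count in any submerged library, at least 931-fold and at least 112-fold lower. Of the genes with a symbol, TR1 (BnaCnng15100D) rose by 0.90 ± 0.17 (log2 fold change ± SE, n = 3, edgeR adjusted p = 0.00204) and KCP1 (BnaA02g32290D) by 0.79 ± 0.11 (edgeR adjusted p = 0.000253). With all 5 libraries with segments left out, which leaves a single Avatar air library, the log2 fold change of TR1 (BnaCnng15100D) was 0.54. C genes rose more often than A genes (22.2% against 20.9%, odds ratio of A over C 0.923), but not without the libraries with silent segments (1.002). A genes fell more often (19.4% against 17.6%, odds ratio 1.127), a difference that did not pass the test among genes at a mean of at least 5 CPM (1.036). Chromosomes C07 and A10 had the highest share of changed genes (both 46.3%). C08, lowered in Avatar submergence replicate 1, had the lowest (30.5%). Inside the silent segments 15.9% of 1699 genes were called, against 41.4% of 50079 genes outside all lowered segments (Fisher's exact test, two-sided, odds ratio 0.268, p = 2.04e-110). Risers were 53.9% of the calls with TMM factors, 73.9% with library totals alone, and 70.7% and 71.3% with limma on log2 TPM with 1 or 0.1 added. They were under 50% with RLE factors and with DESeq2 (both 49.5%), with only the libraries compared (49.4%) and without Avatar submergence replicate 1 (48.2%). Library totals alone raised the median log2 fold change of all genes from 0.11 to 0.45.

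In Zhongshuang 9, submergence raised 12538 genes and lowered 12250, 44.5% of those tested. Of these, 17196 changed at least 2-fold. BnaC09g10140D rose from 1 count in the 3 air libraries together to 44.6 ± 19.3 CPM (SD, n = 3), a ratio of 4190 with a counting interval of 752 to 166000. BnaA08g26000D rose from no count to 17.8 ± 0.318 CPM (SD, n = 3), at least 176-fold. BnaA07g33410D fell from 57.5 ± 10.2 CPM (SD, n = 3) to 2 counts in the 3 submerged libraries together, a ratio of 2880 with a counting interval of 796 to 23700. BnaA05g06830D fell from 19 ± 1.98 CPM (SD, n = 3) to no count, at least 204-fold. TR1 (BnaCnng15100D) rose by 1.16 ± 0.17 and KCP1 (BnaA02g32290D) by 0.79 ± 0.11 (log2 fold change ± SE, n = 3, edgeR adjusted p = 0.000328 and 0.000196). A genes fell more often than C genes (23.4% against 20.8%, odds ratio 1.16, adjusted p of Fisher's exact test = 1.22e-12). C genes rose more often (23% against 22.1%, odds ratio of A over C 0.95), but not without the libraries with silent segments (1.006). Chromosome A01 had the highest share of changed genes (50.7%). C08, lowered in Zhongshuang 9 air replicate 4, had the lowest (35.6%), followed by C02 (36.2%) and C03 (36.8%). On C03 only Avatar libraries had segments. Inside the silent segments 13.1% of 1699 genes were called, against 46.1% of 50079 genes outside all lowered segments (odds ratio 0.176). The test estimates the spread over all 12 libraries, so segments of Avatar libraries enter it as well. Risers were 50.6% of the calls with TMM factors, 65.4% with library totals alone, and 63.2% and 63.3% with limma on log2 TPM with 1 or 0.1 added. They were 48.1% with limma-voom and between 48.8% and 53.9% with single libraries left out. With library totals alone the median log2 fold change of all genes was 0.29 in place of 0.01.

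The cultivars changed largely the same genes in the same direction. Of the genes past the threshold in both, 8772 rose in both and 7945 fell in both, against 2704.5 and 2257.3 for independent lists. Opposite changes occurred in 128 genes, against 4952.7. A further 5423 genes passed the threshold in Avatar only and 7943 in Zhongshuang 9 only, which does not show that their responses differ. Across the 55674 genes the log2 fold changes had Pearson's r = 0.753 and Spearman's rho = 0.745, and 78.5% had the same sign. Genes are not independent replicates, and the comparisons share no library. Among the 24587 genes at a mean of at least 5 CPM, r was 0.838. In both cultivars 16 genes were counted in every submerged library and silent in every air library, 12 of them in the C subgenome. Of the 55674 tested genes 29235 were in C, and whether the 12 exceed that share was not tested. Conversely, 10 genes were counted in every air library and silent in every submerged library.

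**Figure D3:**
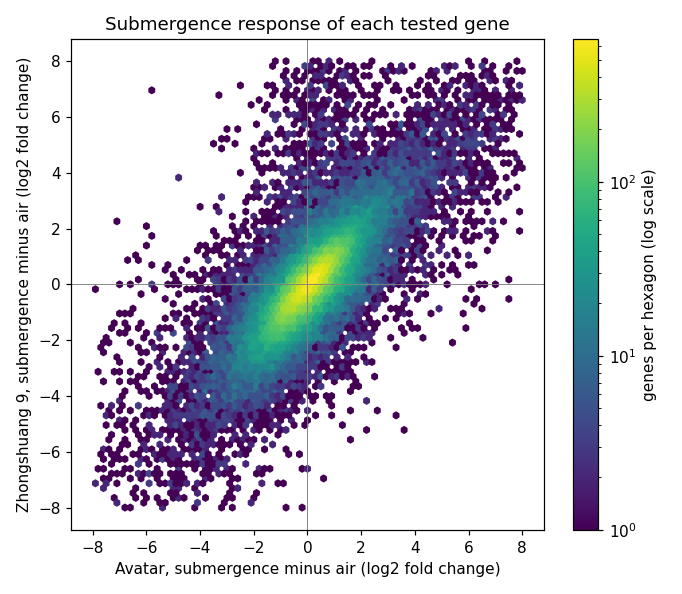
Log2 fold change (submergence minus air) of each tested gene in Avatar (horizontal axis) and Zhongshuang 9 (vertical axis), with colour for the number of genes per hexagon on a log scale; 334 of 55674 genes with a log2 fold change beyond 8 in either cultivar are not drawn. Most genes lie along the rising diagonal (Pearson's r = 0.753 over all genes).

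A direct test of the difference between the responses called 694 genes, 1.2% of those tested. The response was higher in Zhongshuang 9 for 244 of them and lower for 450. Of the 244 genes, 43 changed past the threshold in opposite directions in the cultivars and 89 in the same direction by different amounts. Of the 450 genes, 53 changed in opposite directions and 206 in the same direction. BnaCnng28130D fell in Avatar from 2.98 ± 0.824 to 0.0679 ± 0.0226 CPM (SD, n = 3). In Zhongshuang 9 it was at 4.78 ± 0.333 CPM in air and 7 ± 0.769 CPM under submergence, a difference of 5.91 ± 0.37 in log2 fold change (± SE, edgeR adjusted p = 0.0006). BnaC01g19760D fell from 16.9 ± 1.03 to 7.94 ± 0.474 CPM in Avatar and rose from 10.9 ± 0.577 to 20.9 ± 2.53 CPM in Zhongshuang 9 (edgeR adjusted p of the difference = 0.00168). In the opposite sense, BnaA01g30410D rose from 2.6 ± 0.0847 to 6.2 ± 0.287 CPM in Avatar and fell from 21.1 ± 3.21 to 6.33 ± 0.954 CPM in Zhongshuang 9 (edgeR adjusted p of the difference = 0.00129). BnaC04g18290D rose from 3.78 ± 0.3 to 8.09 ± 1.09 CPM in Avatar and fell from 10.7 ± 1.93 to 1.81 ± 0.444 CPM in Zhongshuang 9 (edgeR adjusted p of the difference = 0.00168). A and C genes were called at shares of 1.2% and 1.3% (odds ratio of A over C 0.973). Without the 5 libraries with segments the odds ratio was 1.281, but a single Avatar air library is then left. The silent segments held 4 of the 694 genes, 0.2% of the 1699 tested there, against 1.3% of 50079 genes outside all lowered segments. On C08, lowered in a Zhongshuang 9 air and an Avatar submergence library, the median difference in log2 fold change was 0.29, against -0.09 over all genes. On C03, with segments in Avatar air replicates 3 and 4, it was -0.34. On C02, with segments in libraries of both cultivars, it was -0.26.

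The 4 genes named for the difference passed the threshold in every alternative, which their choice by the smallest p in the same libraries made likely. The count of genes did not hold. It was 276, 109 and 154 without Zhongshuang 9 air replicate 1, 3 or 4, and 398 and 227 without Zhongshuang 9 submergence replicate 3 or 4. It was 195 and 187 without Avatar air replicate 3 or 4, and 219 and 310 without Avatar submergence replicate 3 or 4. It was 2934 with DESeq2, 2034 and 1056 with limma on log2 TPM with 1 or 0.1 added, and 425 with no filter on low counts. With the replicate number as a block it was 300. The highest count with a single library left out was 887, without Zhongshuang 9 submergence replicate 1. Higher responses in Zhongshuang 9 were 35.2% of the calls with TMM factors, 47.5% with RLE factors, 51.7% with DESeq2 and 50.7% without Avatar submergence replicate 1.

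In air, 3677 genes were higher and 5830 lower in Zhongshuang 9 than in Avatar, 17.1% of those tested. Of these, 7250 differed at least 2-fold. BnaC02g38180D was at 23.8 ± 1.95 CPM in Zhongshuang 9 (SD, n = 3) with no count in Avatar air, at least 217-fold higher. BnaA04g18770D was at 13.4 ± 1.91 CPM in Zhongshuang 9 (SD, n = 3), again with no count in Avatar air. BnaC01g21370D was at 16.2 ± 2.08 CPM in Avatar air with no count in Zhongshuang 9 air, at least 160-fold lower. BnaA09g54870D was at 668 and 481 CPM in Avatar air replicates 1 and 4 but at 0 in replicate 3. It was at 0.305 ± 0.418 CPM (SD, n = 3) in Zhongshuang 9 (log2 fold change -10.34 ± 2.33, SE, edgeR adjusted p = 0.0117). This gene lost its call without Zhongshuang 9 air replicate 3 or 4 (edgeR adjusted p = 0.0586 and 0.0585), with limma-voom and with limma on log2 TPM; its adjusted p over the alternatives ranged from 5.87e-06 with DESeq2 to 0.702 with limma-voom. A genes were lower in Zhongshuang 9 more often than C genes, 13.9% against 7.4% (odds ratio 2.019, interval 1.908 to 2.136, adjusted p of Fisher's exact test = 1.13e-136). This test counts genes as independent, so its interval and p do not measure the spread between samples. Higher genes were 6.6% in each subgenome (odds ratio 1.006, interval 0.941 to 1.077), and 1.129 was the odds ratio without the 5 libraries with segments, which leaves a single Avatar air library. A03 had the highest share of lower genes of the chromosomes (18.7%), and a stretch of it was raised in Avatar air replicates 3 and 4 (median log2 shift 0.99 and 0.55). A05 had the highest share of higher genes (12.2%). C08, lowered in Zhongshuang 9 air replicate 4, had the lowest share of called genes (10.5%). Without Zhongshuang 9 air replicate 3 the count fell to 6209 genes.

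Under submergence the cultivars differed in 13642 genes, 24.5% of those tested: 5713 were higher and 7929 lower in Zhongshuang 9. BnaC02g38180D and BnaA04g18770D stood at 31.5 ± 1.14 and 25.8 ± 5.32 CPM in Zhongshuang 9 (SD, n = 3) with no count in submerged Avatar, at least 402-fold and at least 329-fold higher. BnaC01g21370D was at 42.8 ± 5.2 CPM in Avatar with no count in Zhongshuang 9, at least 459-fold lower. BnaA09g54870D was at 1490 ± 672 CPM in Avatar and 0.0752 ± 0.0753 CPM in Zhongshuang 9 (log2 fold change -14.13 ± 2.70, SE, n = 3, edgeR adjusted p = 0.00359, range over alternatives 2.17e-10 with DESeq2 to 0.439 with limma-voom). A genes were again lower in Zhongshuang 9 more often than C genes, 17.7% against 11.2% (odds ratio 1.704, interval 1.623 to 1.789, adjusted p of Fisher's exact test = 1.65e-104). C genes were higher more often, 10.9% against 9.6% (odds ratio of A over C 0.87), but not without the libraries with silent segments (1.007). Chromosomes A01, A05 and A10 had the highest shares of called genes (34.4%, 33.3% and 31.8%) and C08 the lowest (14.8%). Of the genes past the threshold in both treatments, 2085 were higher and 3941 lower in Zhongshuang 9 each time, against 377.3 and 830.3 for independent lists. Opposite differences occurred in 99 genes. Higher genes were 41.9% of the calls under submergence with TMM factors, 50% with RLE factors and 51.6% with DESeq2.

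**Figure D4:**
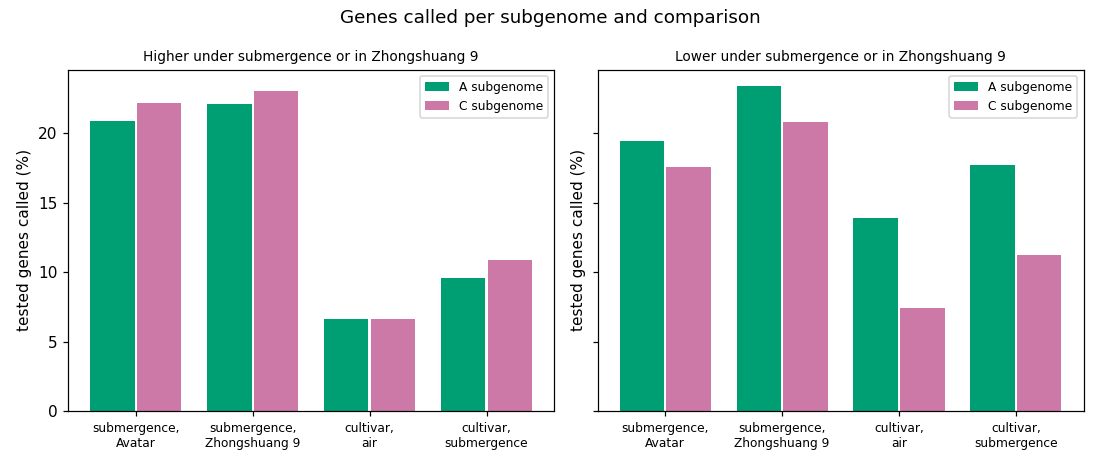
Percent of tested A genes (26280) and C genes (29235) called higher (left) or lower (right) in each comparison, as bars from 0; each bar is a share of genes from a single test over 3 libraries per group, so no error bar is drawn. Genes lower in Zhongshuang 9 than in Avatar were more frequent in A than in C, 13.9% against 7.4% in air and 17.7% against 11.2% under submergence.

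The differences between the cultivars also grouped along A chromosomes. Without Avatar air replicate 3 and Zhongshuang 9 submergence replicate 1, 16 of the 743 blocks of neighbouring genes had a median that differed between cultivars by at least 0.6 log2 units in the same direction in both treatments. All 16 lay among the 366 A blocks, with 13 lower and 3 higher in Zhongshuang 9, and none among the 377 C blocks; shuffled gene positions gave none in any of 100 draws. The higher blocks included A01 at gene numbers 29890 to 30870, with 1.06 in air and 1.07 under submergence (0.69 under submergence over all libraries), and A05 at 33630 to 34440, with 0.97 and 0.93 (1.01 and 0.93 over all libraries). Over all libraries 1 of the 16 blocks, on A10 at 23500 to 24810, was under the minimum, at -0.46 under submergence. Adjacent lower blocks lay on A05 at 6990 to 9110 (-0.72 and -0.86 in air, -0.91 and -0.76 under submergence) and on A10 at 25620 to 27250 (-0.88 and -0.68 in air, -0.89 and -1.08 under submergence). Over all 12 libraries, 77 genes were counted in every Avatar library and silent in every Zhongshuang 9 library, and 47 the other way round. These fell to 9 and 6 when at least 5 CPM against no count was required. Without Zhongshuang 9 submergence replicate 1 these were 158 and 72, and of the 158 genes 69 were in A and 88 in C.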

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

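The other splits of the libraries were chosen before the data were examined, and the comparison of their spread after the result was seen. The interaction count and the 4 genes named for it stand out because the submergence effect differed between cultivars in a direct test of that difference. The count was 694 genes. Cultivar labels were exchanged within each treatment in 100 draws, the real assignment included, and 3 of the 100 gave as many genes (highest other count 1660, followed by 808). Exchanged labels mix the cultivars: the biological coefficient of variation was 0.354 for the real assignment and between 0.463 and 0.58 in each of the other 99, of which 78 called no gene. The draws therefore leave open whether the count arose by chance. The 1660 genes came from a split that kept the air libraries and exchanged 2 submerged libraries of each cultivar. The 808 genes came from a split that exchanged all submerged libraries but kept most air libraries. Unequal exchange between treatments puts part of the difference between cultivars into the interaction contrast. Such splits hold a real difference, so the 3 of 100 do not measure chance. How far this raised their counts was not tested.

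Among the named genes, the difference in submergence log2 fold change (Zhongshuang 9 minus Avatar) was 5.91 for BnaCnng28130D, 2.02 for BnaC01g19760D, -2.99 for BnaA01g30410D and -3.66 for BnaC04g18290D. All 4 kept their direction and passed the threshold in each alternative in which they were tested. Having been chosen by the smallest p in the same libraries, they were likely to do so.

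For the comparisons of 3 against 3 libraries, 10 splits exist, so no share under 0.05 can be reached. The real count was the highest in each, as 1 split of the 10: 22268 genes for submergence in Avatar (highest other 20), 24788 for submergence in Zhongshuang 9 (highest other 0), 9507 for the cultivars in air (highest other 0) and 13642 for the cultivars under submergence (highest other 19). The other splits mix groups that differ, and their biological coefficient of variation was 0.463 to 0.525, against 0.354. The exchange itself thus lowers their counts, so these splits do not tell whether chance gave the real counts.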

How the results depend on the processing

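Leaving out the libraries or genes of the segments was chosen after the data were examined. Numbers of genes called stayed within 1.5 times the reported count for the submergence and cultivar comparisons, with 2 exceptions: 14427 genes for Avatar submergence with a minimum absolute log2 fold change of 1, and 6209 for the cultivars in air without Zhongshuang 9 air replicate 3 (range 6209 to 12490 over single libraries left out), where fewer libraries were used. The interaction gave 2934 genes with DESeq2, 2034 and 1056 with limma on log2 TPM with 1 or 0.1 added, 425 with no filter on low counts and from 109 to 887 with single libraries left out; the cause was not tested. Among single libraries left out, Zhongshuang 9 submergence replicate 1 gave the highest count for the interaction (887) and for submergence in Avatar (25886). It also did so for the cultivars in air (12490) and under submergence (15373). For submergence in Zhongshuang 9 the highest count was 25645, without Avatar submergence replicate 1. The replicate numbers did not pair the libraries: 1 of 18 same-numbered pairs correlated above 0.1 (range -0.15 to 0.11) and 1 of 12 libraries was closest to its own number in every other group. With the replicate block the interaction called 300 genes; the block moved no other count by over 1.5 times.

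The correlation of the responses was 0.838 for genes of at least 5 CPM, 0.692 to 0.782 with single libraries left out, and 0.669 without the 5 libraries with segments, where a single Avatar air library is assumed to vary like the other groups. Odds ratios of A over C turned or lost their call for risers in Avatar (1.002 without the libraries with silent segments, 1.015 without all 5), risers in Zhongshuang 9 (1.006 and 1.007), genes higher in Zhongshuang 9 under submergence (1.007 and 0.998) and fallers in Avatar at 5 CPM or more (1.036). Without all 5, where a single Avatar air library is left, the odds ratios were 1.281 for the interaction and 1.129 for genes higher in Zhongshuang 9 in air. Those for genes lower in Zhongshuang 9 kept their call each time. Genes counted in a single cultivar numbered 158 (Avatar) and 72 (Zhongshuang 9) without Zhongshuang 9 submergence replicate 1, and 9 and 6 when at least 5 CPM against no count was required. The causes were not tested. Of 596 alternative values of named genes, 589 kept direction and threshold, 7 kept direction only and 0 turned. Apart from the genes with a symbol, these were chosen for large fold changes or small p in the same libraries. Their stability was thus likely in advance and does not speak for other genes. The interaction needs all groups, so it has no fit on fewer. Alternatives for the 34 gene lists were not run, since the lists could not be evaluated. At this depth a count of 0 allows up to 0.123 CPM in a library. Genes called silent may have up to 2 counts, so their level may lie above that floor.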

Other observations

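The tests below were chosen after the result was seen, except that of paired genes in Zhongshuang 9 submergence replicate 1 and those of the shifted blocks and of A among genes counted in Avatar only. Silent or lowered C segments occurred in single libraries of both cultivars and both treatments. Raised A segments, on A02 and A03 in Avatar air replicate 3 and on A02 in Zhongshuang 9 submergence replicate 1, went with silent C02 and C03 stretches, to which these parts are largely collinear in Brassica. Too few reads is argued against by a median count of 196 for the genes of the C03 segment in the other Avatar air libraries, and a library of the other cultivar by the 5 of 52 genes counted only in Zhongshuang 9 that had over 2 counts in Avatar air replicate 3. As a hypothesis, A chromosome copies may have taken the place of C copies in these plants: A03 was higher by 0.99 (log2) where C03 was silent and by 0.55 where C03 stood at 53.2%, and A02 by 0.41 where C02 stood at 58.1%. For the lowered C08, neither A08 nor A09 rose as a whole in Avatar submergence replicate 1 or Zhongshuang 9 air replicate 4 (highest median 0.05). This argues against a rise along all of A08 or all of A09. The medians cover whole chromosomes, so a rise over a part of either could be missed, and the same hypothesis stays open for parts. A lost C08 copy was not tested.

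Zhongshuang 9 submergence replicate 1 carried a different set of silent genes from the rest of its cultivar. Avatar RNA mixed in cannot alone account for this, because 276 genes had at least 10 counts there and at most 2 counts in each of the other 11 libraries. Any other library had at most 36 such genes. Genes silent in both cultivars do not tell whether some Avatar RNA was present as well. An Avatar library under a wrong label is argued against by 54 of 72 genes counted only in the other Zhongshuang 9 libraries that had over 2 counts there. A plant of another genotype with chromosome stretches in common with Avatar may explain it. The 139 placed genes counted only in Avatar were paired with the next such gene on their chromosome, at any distance. Of these 120 pairs, 65% had the same state in this library (over 2 counts or not), against 50% under shuffling (permutation test, one-sided, p = 0.00066). Genes inside the segments of this library were not left out, so like states there could add to the share. Which genotype such a plant would be, and whether seeds or samples were mixed, cannot be settled from counts.

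Genes lower in Zhongshuang 9 than in Avatar were more frequent in the A subgenome. Under submergence the 5 libraries with segments do not explain this, since the odds ratio without them was 1.611, with 2 libraries left per group. In air it was 1.873 without them, but a single Avatar library is then assumed to vary like the other groups. Avatar air libraries correlated at 0.918 to 0.955 with each other and those of Zhongshuang 9 air at 0.977 to 0.984. The value in air therefore does not decide the question. The 16 shifted blocks do not explain it, since without them the odds ratio was 1.893 in air (interval 1.787 to 2.005). A copies that differ in sequence from the annotation used by the authors could lower the counts, and this cannot be told apart from lower expression because no sequences were analysed here; among genes counted in Avatar only, the odds ratio of A over C was 0.872 (interval 0.627 to 1.209).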
